A study of Sus scrofa with 4 samples.

How the data were processed

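RNA of 4 libraries of porcine fetal fibroblasts was analysed, 2 labelled as controls and 2 as over-expressing BRG1, in the groups and with the replicate numbers that the sample titles give. The deposited files hold whole-number counts of reads per Ensembl gene, 1 file per library, not normalized. Per the submitters' processing notes, FastQC, STAR, SAMtools, Cufflinks, DESeq2 and edgeR were used on the pig build Sscrofa11.1; which read counter, strand setting and annotation release made the counts is not given in the sources used here, so overlapping and antisense genes cannot be told apart. Per the labels' protocols, total RNA was extracted with trizol. Each file lists 35670 genes, of which 17508 carry a symbol; 223 more symbols were taken from the gene name table for the same identifiers, and 17939 genes have none. The closing rows that name no gene were kept out of library sizes and tests. Reads outside annotated genes made up 6.11% and 7.34% of all reads listed in controls 1 and 2, and 10.3% and 10.5% in the libraries labelled BRG1; reads that fell on more than 1 gene made up 2.33%, 2.14%, 1.91% and 1.90%, and reads aligned to more than 1 place 1.80%, 1.60%, 1.42% and 1.42%. Such reads are lost to genes with close paralogs or pseudogenes.

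Counts per gene summed to between 34486400 and 38126860 per library. The fits were made in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM (factors 0.918, 0.931, 1.08 and 1.08 for controls 1 and 2 and the libraries labelled BRG1), and the group was tested with the quasi-likelihood F test without robust estimation. P-values were adjusted by Benjamini-Hochberg over the 14617 genes tested, with a threshold of 0.05; the common biological coefficient of variation was 0.113. Log2 fold changes are those of the fit with a prior count of 0.125, and the standard error (SE) is the unshrunk log2 fold change divided by the square root of F. CPM values are scaled by TMM and given as mean ± SD over 2 libraries.

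Before the data were examined, 37 gene lists were fixed: pathways of chromatin, cell cycle, matrix, signalling, inflammation and metabolism, signs of RNA quality, and markers of other cell types that skin could contain. All 37 had at least 5 tested members. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation no list passed, not even DNA replication (adjusted p = 0.387), whose estimated correlation of 0.001 lay below the preset 0.01. With 2 libraries per group that version could hardly call any list, so its p-values do not tell lists apart. Estimates lay far above the preset value for ribosomal protein (0.962), oxidative phosphorylation (0.733), matrix (0.649) and interferon-stimulated genes (0.406). They lay closer to it for contractile (0.036) and glycolysis genes (0.023). Where members move together that much, the p-values at the preset correlation are too small. Named genes follow a rule fixed at the same time: SMARCA4, the 12 largest rises and 12 largest falls among genes past the threshold with a symbol, a mean log2 CPM of at least 2 and both libraries of one group on the same side of the other, the 6 smallest adjusted p values, and up to 4 members of each list with the smallest adjusted p. The rule gives 152 genes past the threshold; which of them serve as examples was chosen after their values were seen. The value of 1 gene of the cholesterol synthesis list is not reported here.

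Replicates were compared before averaging. The correlation of log2 CPM was 0.983 between controls and 0.988 between the libraries labelled BRG1, against 0.948 to 0.952 between groups, and chi-square per degree of freedom was 40.1 and 5.34, so that both pairs differed by more than counting noise. The test was checked on simulated counts drawn from these libraries' means and sizes with 200 genes changed. Of these, 73 of 100 genes changed 2-fold and 81 of 100 changed 4-fold were recovered, with 11 false calls among 14317 genes. Genes were drawn independently with the same dispersion in both groups, so this does not measure the rate of false calls in the data. The alternatives were other scalings, other filters on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, stricter thresholds, each library left out in turn and, added after the data were seen, removal of each library's trend with gene span. Gene spans were taken by symbol from a RefSeq table of the same build and were found for 77.5% of genes tested and 93.2% of those with a symbol, so checks over all tested genes cover only genes with a span.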

Results

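RNA was sequenced from porcine fetal fibroblasts, skin cells of pig fetuses used as nuclear donors in cloning, which had been starved of serum. The labels give 2 groups of 2 libraries each: controls of wild-type genotype, and cells labelled as over-expressing BRG1, the ATPase of the BAF (SWI/SNF) chromatin remodelling complex, encoded by SMARCA4. The deposited gene counts summed to 38126860 and 34486400 in controls 1 and 2, and to 36238580 and 34684837 in the libraries labelled BRG1. The series' design text names the question: what more BRG1 in donor cells does to chromatin before nuclear transfer. The titles of both groups carry the name pTK-642, which the sources used here do not explain, so it is not known whether the controls carry a vector. The labels do not say that the libraries of a group come from separate cultures, so the p-values measure only the spread between these samples.

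SMARCA4 (ENSSSCG00000013629; Sscrofa11.1 chromosome 2, 69717175 to 69810301) was not higher in the libraries labelled BRG1. Its level was 167 ± 17.1 CPM (counts scaled by library size and TMM factors; SD, n = 2) in controls and 162 ± 2.82 in the libraries labelled BRG1, from 5406, 5734, 6255 and 6119 reads. The log2 fold change was -0.04 ± 0.10 (SE; adjusted p = 0.765, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), with a 95% interval from -0.27 to 0.18, or 0.83-fold to 1.13-fold. The deposited counts therefore do not check the label by this gene, and every direction below is that of the libraries labelled BRG1 against the controls. Reads of an introduced coding sequence need not be counted under the pig gene, and the species of that sequence is not given in the sources used here. The value was 0.05 without control 2, 0.18 with scaling by library size alone, and it passed the test as lower without control 1 (-0.15; adjusted p = 0.0251) and with each library's trend with gene span removed (-0.26; adjusted p = 0.0348).

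**Figure D1:**
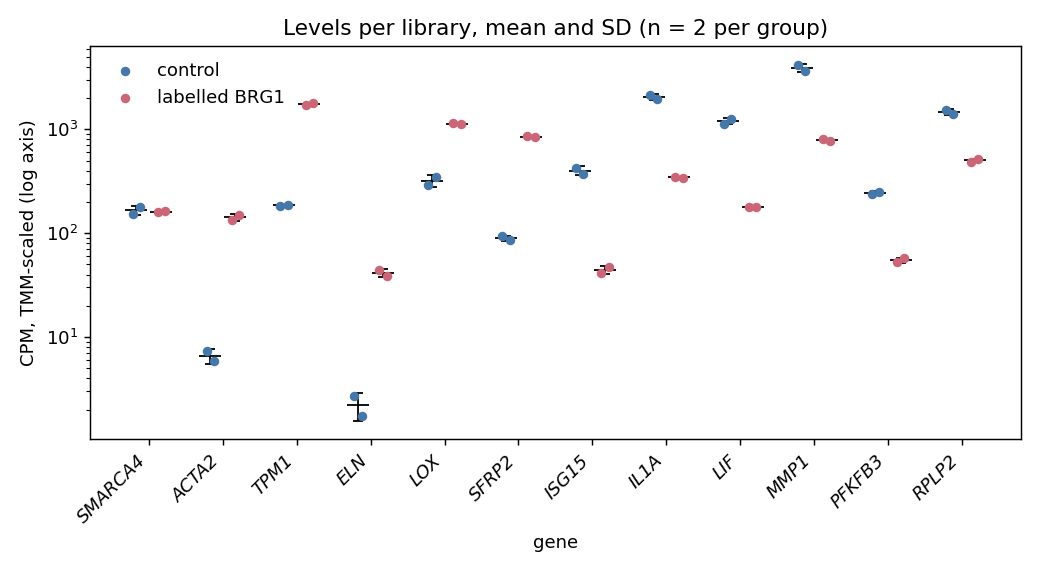
CPM (scaled by TMM, log axis) of 12 genes in each of the 4 libraries, controls in blue and libraries labelled BRG1 in red, with the mean (horizontal mark) and SD (bars, n = 2). SMARCA4 overlaps between the groups (167 and 162 CPM), ACTA2 lies at 6.57 CPM in controls against 142, and IL1A at 2063 against 346.

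Of 14617 genes tested, 6512 (44.6%) passed an adjusted p of 0.05, 3068 of them higher and 3444 lower in the libraries labelled BRG1; 1267 rose and 917 fell at least 2-fold. In 6511 of the 6512 both libraries of one group lay above both of the other, as they did in 10702 of all genes tested, against the 33.3% that chance gives. With scaling by library size alone the median of all genes moved by 0.23 on the log2 scale, and the split was 4820 higher and 2139 lower. Without library 1 labelled BRG1 the counts were 1908 and 2177, and without library 2 they were 1979 and 2250. Genes named in the rest of this part come from a rule fixed before the data were examined, which gives 152 genes past the threshold. Which of them are named was chosen after their values were seen.

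Genes of the contractile apparatus and of the extracellular matrix rose in the libraries labelled BRG1. ACTA2, smooth muscle alpha-actin, rose from 6.57 ± 1.05 to 142 ± 10.5 CPM (log2 fold change 4.43 ± 0.14), and TPM1, a tropomyosin that lies along actin filaments, from 186 ± 2.81 to 1756 ± 31.2 (3.24 ± 0.12). ACTG2, a gamma-actin of smooth muscle, rose by 3.31 ± 0.14 on the log2 scale, and TAGLN, the actin-binding transgelin, by 2.22 ± 0.11. ELN, which encodes elastin, rose from 2.21 ± 0.67 to 41.5 ± 3.70 CPM, LOX, the enzyme that crosslinks collagen and elastin, from 321 ± 43.4 to 1139 ± 16.8, and COL14A1, a fibril-associated collagen, from 152 ± 25.9 to 688 ± 9.94.

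Of 20 contractile genes tested, 16 rose and 2 fell, and of 38 matrix genes 32 rose and 3 fell, with medians of 1.02 and 1.00 on the log2 scale. For these and all later lists, the count adjusted over the list alone was the same unless a second count is given. In camera with a preset correlation of 0.01, adjusted over the 37 lists, both stood apart from other genes (adjusted p = 6.47e-21 and 2.73e-20). With an estimated correlation neither did (adjusted p = 0.277 and 0.581), but no list passed in that version. The estimates were 0.036 for the contractile list and 0.649 for the matrix list. At the preset 0.01 the p-value of the matrix list is therefore likely too small. In fry the contractile list passed (adjusted p = 0.0134) and the matrix list did not (adjusted p = 0.0626). Without library 1 or library 2 labelled BRG1, 12 contractile and 27 matrix genes rose and 0 fell. Reads shared between the near-identical actin genes could not be resolved from the counts. Among 9 cartilage and bone markers 4 rose and 1 fell, or 5 and 1 adjusted over the list alone, with COL11A1, a fibrillar collagen, at 2.78 ± 0.13 (camera adjusted p = 0.0221; adjusted p = 0.685 with an estimated correlation). That list no longer passed without control 1 (adjusted p = 0.0629), and its rises numbered 2 without library 1 labelled BRG1 and 1 without library 2.

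Of 24 targets and regulators of WNT signalling tested, 14 rose and 2 fell, or 17 and 2 adjusted over the list alone (camera adjusted p = 1.46e-07; adjusted p = 0.316 with an estimated correlation). SFRP2, a secreted protein that binds WNT ligands, rose from 89.7 ± 5.17 to 848 ± 10.7 CPM (3.24 ± 0.11), and SFRP1 from 360 ± 32.2 to 1255 ± 10.1. DKK2, a secreted modulator of the WNT co-receptors, had the largest rise of the named genes, from 0.16 ± 0.05 to 8.66 ± 0.66 CPM (5.70 ± 0.36; 7 and 4 reads in controls). In the TGF-beta response list 9 genes rose, led by PMEPA1 (2.21 ± 0.12) and CCN2 (2.21 ± 0.12), and 9 fell, among them LTBP1 (-1.11 ± 0.12). The list as a whole did not pass (camera adjusted p = 0.343); its median was -0.01, its mean 0.17, and its median 0.21 with scaling by library size alone, 0.13 without control 2 (11 rose and 9 fell) and -0.06 without control 1.

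Inflammatory cytokines and interferon-stimulated genes fell. IL1A, the cytokine interleukin-1 alpha, fell from 2063 ± 141 to 346 ± 4.78 CPM (log2 fold change -2.58 ± 0.12), LIF, a cytokine of the interleukin-6 family, from 1198 ± 83.5 to 179 ± 1.26 (-2.74 ± 0.12), and CSF3, a granulocyte growth factor, from 1462 ± 125 to 282 ± 1.83 (-2.38 ± 0.12). ISG15, a ubiquitin-like protein induced by interferon, fell from 400 ± 39.5 to 44.4 ± 3.72 CPM (-3.17 ± 0.12), IFI6 from 903 ± 171 to 164 ± 3.42, and CXCL10, a chemokine, from 104 ± 10.8 to 18.6 ± 1.00. All 34 interferon-stimulated genes tested fell (median -1.68), as did 23 of 26 inflammatory genes (median -1.72), while 3 rose. Both lists passed in camera (adjusted p = 9.09e-44 and 1.21e-32), and neither with an estimated correlation (adjusted p = 0.316 and 0.303 with an estimated correlation). Their estimated correlations, 0.406 and 0.149, lay above the preset 0.01, so the p-values at the preset value are likely too small.

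The collagenase MMP1 fell from 3920 ± 363 to 788 ± 17.8 CPM and the stromelysin MMP3 from 208 ± 26.7 to 49.4 ± 3.24, as did TIMP1, an inhibitor of such proteases, from 1840 ± 91.6 to 644 ± 11.8. Of 18 matrix proteases and inhibitors 10 fell and 3 rose, or 11 and 5 without control 2 and 8 and 6 with scaling by library size alone (camera adjusted p = 0.000115; adjusted p = 0.685 with an estimated correlation). Their median of -0.36 (95% interval -1.43 to 0.10) was -0.13 with library size alone and -0.17 (-1.26 to 0.06) with the trend with gene span removed. Both intervals resample genes and not libraries. Other falls among the 12 largest were those of ELF3, an epithelial transcription factor (-2.90 ± 0.15) and MT1X, a metallothionein that binds zinc and copper (-2.67 ± 0.13). MT1X has close paralogs whose reads may be divided among them. Of 23 immediate early and AP-1 genes 3 rose and 8 fell, with FOSL1, an AP-1 subunit, at -1.58 ± 0.12 and NR4A1, an orphan nuclear receptor, at 1.37 ± 0.10. That list did not pass (camera adjusted p = 0.436), its median of -0.09 turned to 0.14 with scaling by library size alone and to 0.01 without control 2, and its counts were 8 and 8 without control 2, 8 and 6 with library size alone, and 7 and 5 with the trend with gene span removed.

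**Figure D2:**
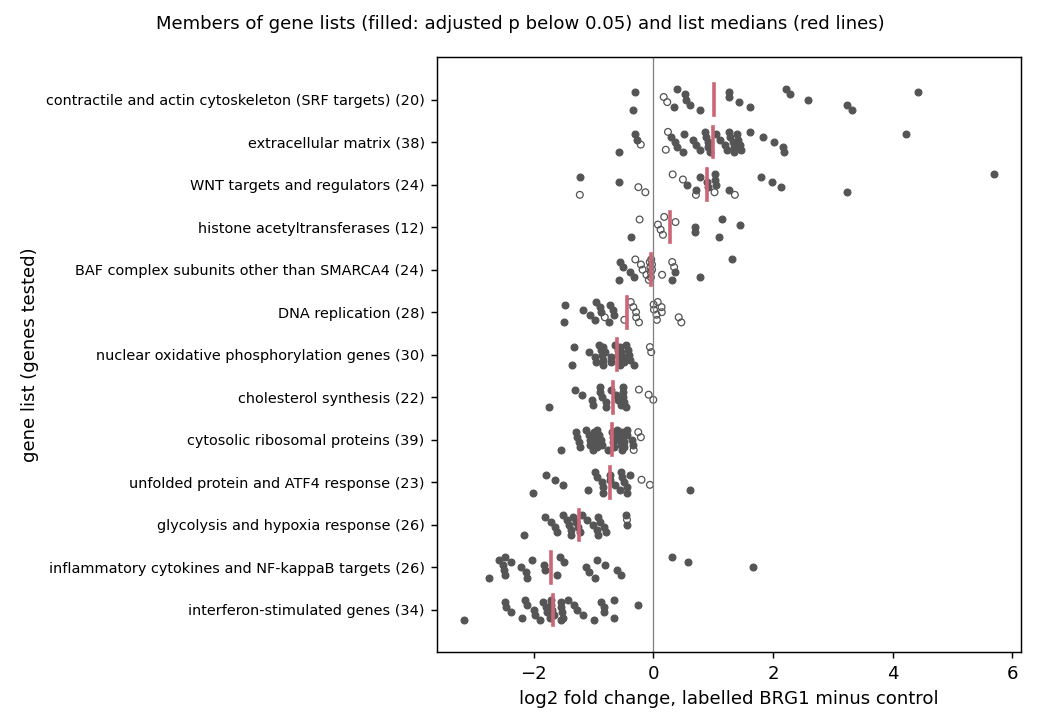
Log2 fold change (horizontal axis, libraries labelled BRG1 minus controls) of each tested member of 13 gene lists, filled where the adjusted p was below 0.05, with the list median as a red line. All 34 interferon-stimulated genes lie below 0, and 16 of 20 contractile genes are filled points above 0; with scaling by library size alone the BAF median turned from -0.05 to 0.18.

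Most tested genes of the glycolysis and hypoxia, unfolded protein and ATF4, cholesterol synthesis and NRF2 lists fell. PFKFB3, which makes the activator of the glycolytic enzyme phosphofructokinase, fell from 246 ± 8.12 to 55.1 ± 3.02 CPM (-2.16 ± 0.11), and HK2, a hexokinase, from 226 ± 25.4 to 72.2 ± 1.85. Of 26 glycolysis and hypoxia genes 25 fell (median -1.25; camera adjusted p = 1.19e-25; adjusted p = 0.277 with an estimated correlation). Of 23 genes of the unfolded protein and ATF4 response 20 fell and 1 rose, among the falls CHAC1, which degrades glutathione (-2.01 ± 0.11), and TRIB3, a pseudokinase induced by stress (-1.79 ± 0.10). Of 22 cholesterol synthesis genes 19 fell, among them INSIG1, a sterol-regulated protein of the endoplasmic reticulum (-1.01 ± 0.10). Of 16 NRF2 antioxidant genes 12 fell, with TXNRD1, thioredoxin reductase, at -1.09 ± 0.10. Camera gave adjusted p values of 1.03e-10, 3.48e-08 and 1.97e-05 for these 3 lists, against adjusted p = 0.316, 0.316 and 0.387 with an estimated correlation. Without library 1 labelled BRG1 the falls in the unfolded protein and ATF4 list numbered 14, and without library 2 they numbered 13.

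Cytosolic ribosomal proteins fell in 36 of 39 genes, or 37 adjusted over the list alone (median -0.69), with RPLP2 at -1.54 ± 0.11, and nuclear genes of oxidative phosphorylation fell in 28 of 30 (median -0.62), with UQCRC1, a subunit of respiratory complex III, at -1.33 ± 0.10. Camera gave adjusted p = 9.53e-14 and 3.48e-08 for these lists, and adjusted p = 0.692 for both with an estimated correlation. Ribosomal protein genes have many processed pseudogenes, so their reads may be partly set aside or misplaced. The size of both falls depended on the control used. The ribosomal protein median was -0.49 without control 1 and -0.88 without control 2, and the oxidative phosphorylation median -0.55 and -0.77. Without library 1 labelled BRG1 22 ribosomal protein genes fell and without library 2, 23; the oxidative phosphorylation count was 18 without library 2 and 18 with scaling by library size alone. Beside these lists stood a difference between the libraries: reads outside annotated genes made up 6.72% ± 0.87 of the total in controls and 10.4% ± 0.18 in the libraries labelled BRG1 (SD, n = 2), a difference that an exact permutation test of 2 against 2 cannot bring below p = 0.333. The log2 fold change also increased with the length of genome a gene spans (Spearman correlation 0.29 across genes, which are not independent replicates).

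**Figure D3:**
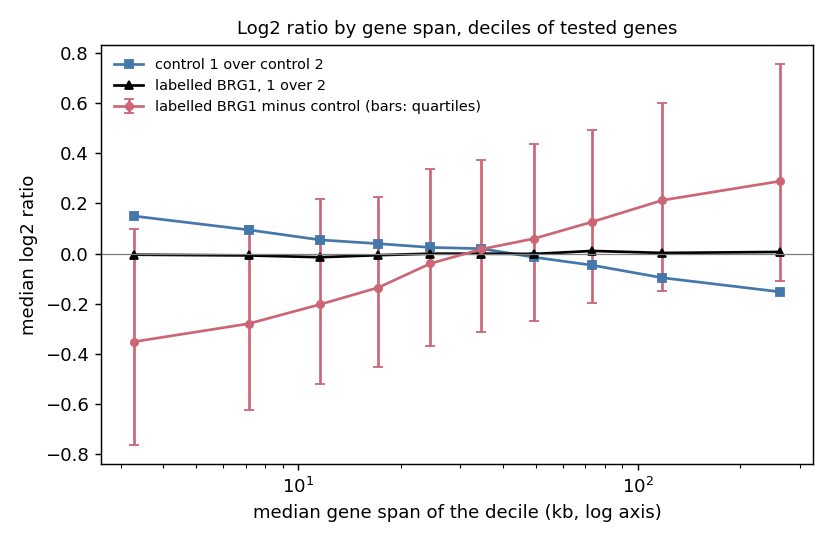
Median log2 ratio (vertical axis) of tested genes in deciles of gene span (horizontal axis, kb, log scale), for the libraries labelled BRG1 minus controls (red, bars from the lower to the upper quartile), for control 1 over control 2 (blue) and for the 2 libraries labelled BRG1 (black). The red line goes from -0.35 in the shortest decile to 0.29 in the longest, and the blue line from 0.15 to -0.15.

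Mitochondrially encoded genes as a list did not pass (1 of 12 rose and 2 fell; median -0.02, or 0.21 with scaling by library size alone; camera adjusted p = 0.897), with 3 rises and 4 falls without control 1, where the median turned to 0.04. These counts were 2 and 7 without control 2, 0 and 0 without library 1 labelled BRG1, and 1 and 0 without library 2. With the trend with gene span removed 8 rose and 0 fell (median 0.43), and the list passed as higher (adjusted p = 0.000125 in camera on signed gene statistics). The median span of this list, 0.87 kb, lay below the 3.28 kb of the shortest decile, whose median log2 fold change was -0.35. Removing the trend raises genes that short by itself, so the rise in that fit decides nothing about mitochondrially encoded genes. With library size alone 4 rose and 0 fell. In the list of heat shock proteins 1 of 13 rose and 5 fell (median -0.19, or 0.04 with scaling by library size alone; camera adjusted p = 0.455), with 0 falls without library 1 or library 2 labelled BRG1, 8 without control 1 and 9 without control 2. With library size alone 3 rose and 1 fell, and with the span trend removed 2 fell.

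Of 28 replication genes tested 12 fell and of 24 mitotic genes 4 rose, or 3 adjusted over the list alone. The others did not pass, though 3 replication genes rose with scaling by library size alone. MCM10, a replication initiation factor, fell from 21.3 ± 0.75 to 7.58 ± 0.27 CPM (-1.49 ± 0.15), and PCNA, the sliding clamp of the replicative polymerases, from 59.8 ± 9.75 to 30.5 ± 0.67. TOP2A, a topoisomerase of dividing cells, rose from 26.4 ± 0.62 to 55.7 ± 0.55 CPM. The replication list passed in camera (adjusted p = 0.0152; adjusted p = 0.387 with an estimated correlation) but not without control 1 or without control 2 (adjusted p = 0.153 in both). The mitotic list did not pass (adjusted p = 0.779). Without control 2 it held 4 rises and 4 falls, without control 1 it held 2 falls, and without library 1 labelled BRG1 it held 2 rises.

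Among p53 targets and cell cycle inhibitors 6 of 21 rose and 5 fell. PLK3, a stress-responsive kinase, fell by 1.59 ± 0.11 on the log2 scale and CDKN2A, a cell cycle inhibitor locus, by 1.10 ± 0.16, while GADD45B, a stress-induced growth arrest gene, rose by 1.07 ± 0.11. The list did not pass (camera adjusted p = 0.897), its median of 0.21 and mean of -0.003 differed in sign, and the median was 0.02 without control 2. Without library 2 labelled BRG1 it held 3 falls, and with library size alone 10 rises and 4 falls. Of 20 apoptosis regulators 10 fell and 2 rose, with BAK1, a pore-forming protein of the mitochondrial membrane, at -1.37 ± 0.13 (camera adjusted p = 0.0617); 6 fell without library 2 labelled BRG1 and 5 with scaling by library size alone. The apoptosis list passed without control 2 (adjusted p = 0.0277, with 13 falls), without library 1 labelled BRG1 (adjusted p = 0.0485) and without library 2 (adjusted p = 0.0337).

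Genes of the chromatin machinery, to which the study's question refers, changed in both directions. Of 24 other BAF subunits 4 rose and 5 fell, or 2 and 2 adjusted over the list alone: SMARCD3, a subunit of muscle and neural forms of the complex, rose from 6.07 ± 0.96 to 15.1 ± 0.74 CPM (1.31 ± 0.17), and PHF10, a subunit of the PBAF form, from 42.0 ± 0.05 to 72.3 ± 0.17. Histone acetyltransferases were the only list of chromatin enzymes to pass (5 of 12 rose and 1 fell; camera adjusted p = 0.0232, but 0.0836 without control 1 and 0.0691 with the trend with gene span removed; adjusted p = 0.626 with an estimated correlation), with KAT2B at 1.46 ± 0.15, KAT6B at 1.14 ± 0.14 and NCOA3 at 1.10 ± 0.12. HDAC1, a deacetylase, fell by 0.60 ± 0.10 on the log2 scale, and 1 of 17 deacetylases rose and 6 fell, or 3 and 7 adjusted over the list alone. Of 27 histone methyltransferases 9 rose and 1 fell, or 7 and 1 adjusted over the list alone, with NSD1 at 0.73 ± 0.14. Of 18 histone demethylases 3 rose and 5 fell, with KDM5B, which removes methyl groups from lysine 4 of histone H3, at -0.55 ± 0.10. Of 13 DNA methylation genes 1 rose and 3 fell, with MBD3, a subunit of the NuRD complex, at -0.86 ± 0.11, and of 20 other remodellers 7 rose and 2 fell, with SMARCA1 at 0.61 ± 0.12.

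Camera gave adjusted p = 0.897 for the BAF list, 0.748 for deacetylases, 0.351 for methyltransferases, 0.724 for demethylases, 0.823 for DNA methylation and 0.343 for other remodellers; methyltransferases passed without control 2 (adjusted p = 0.0236). The medians of the BAF (-0.05), deacetylase (-0.15), demethylase (-0.13) and DNA methylation (-0.11) lists turned to 0.18, 0.08, 0.10 and 0.12 with scaling by library size alone, and the BAF mean was 0.001. With that scaling 7 BAF subunits rose and 0 fell, 7 deacetylases rose and 3 fell, 4 demethylases rose and 2 fell, and 4 DNA methylation genes rose and 1 fell, while 9 acetyltransferases and 11 of the other remodellers rose and 0 fell. With the trend with gene span removed 1 demethylase rose and 8 fell, and that list passed as lower (adjusted p = 0.0394 in camera on signed gene statistics). The value of 0.0691 for acetyltransferases came from the same version of camera, so the change of list test may have moved both calls as well as the trend. The demethylase median, which rests on no list test, went from -0.13 (95% interval -0.33 to 0.05) to -0.32 (-0.56 to -0.10) with the trend removed. The acetyltransferase median went from 0.27 (95% interval 0.10 to 0.90) to 0.26 (-0.09 to 0.57) with the trend removed, an interval that includes 0. The intervals of these 2 lists resample genes and not libraries, so they do not measure the spread between libraries. For these medians the trend was taken from the log2 fold changes, without a new fit. In the fit with each library's trend with gene span removed 3 BAF subunits rose and 9 fell, and 3 methyltransferases rose and 3 fell. There 1 of the other remodellers rose and 5 fell, and 0 DNA methylation genes rose and 5 fell. These counts moved with single libraries (higher and lower in turn). Without library 1 labelled BRG1 they were 2 and 1 for BAF subunits, 1 and 0 for other remodellers, 0 and 3 for deacetylases, 5 and 0 for methyltransferases, 0 and 2 for demethylases, and 5 and 0 for acetyltransferases. Without library 2 labelled BRG1 they were 2 and 1 for BAF subunits, 3 and 0 for other remodellers, 1 and 3 for demethylases, and 5 and 0 for acetyltransferases. Without control 1 they were 4 and 9 for BAF subunits, 7 and 4 for other remodellers, 2 and 6 for deacetylases, 9 and 5 for methyltransferases, 3 and 9 for demethylases, 1 and 5 for DNA methylation genes, and 6 and 2 for acetyltransferases. Without control 2 they were 12 and 1 for other remodellers, 5 and 9 for deacetylases, and 4 and 5 for DNA methylation genes, whose median turned to 0.03.

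Lists tied to early development did not pass. PEG10, an imprinted gene derived from a retrotransposon, rose from 137 ± 30.3 to 485 ± 5.18 CPM and PHLDA2, an imprinted growth regulator, fell from 96.7 ± 22.7 to 43.0 ± 1.83. Of 16 imprinted genes 3 rose and 4 fell, or 6 and 3 with scaling by library size alone (camera adjusted p = 0.897). Of 18 HOX genes HOXA2 alone passed, rising from 2.06 ± 0.49 to 9.89 ± 0.33 CPM (camera adjusted p = 0.436 for the list; 2 rose without control 1, 3 with library size alone and 4 with the span trend removed). Of 9 tested pluripotency and early embryo factors 2 rose and 1 fell, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.897). The fall was that of TBX3, a T-box transcription factor, at -0.70 ± 0.12. In this list 2 fell without control 1, while the rises numbered 0 without library 2 labelled BRG1 and 4 with library size alone.

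Apart from the cartilage and bone markers above, the lists of markers of other cell types did not pass. Of the tested leukocyte markers 1 of 10 rose and 4 fell, with CD14, a receptor for bacterial lipopolysaccharide, falling from 81.5 ± 1.05 to 42.3 ± 0.10 CPM beside the inflammatory genes. Of the endothelial markers 2 of 9 rose and 2 fell, or 2 and 3 adjusted over the list alone, with ERG, an endothelial transcription factor, at 1.62 ± 0.13. Of the adipocyte markers 2 of 7 rose and 1 fell. Of the melanocyte, Schwann and neural markers 2 of 10 rose and 4 fell. Of the keratinocyte markers 1 of 6 rose and 2 fell, or 1 and 3 adjusted over the list alone, and of 6 skeletal muscle markers 1 fell and the others did not pass. The camera adjusted p values in this order were 0.436, 0.823, 0.897, 0.837, 0.863 and 0.897. Single libraries moved some of these counts: without control 2, 3 leukocyte markers rose and 2 neural markers and 0 skeletal muscle markers fell, and without library 1 or library 2 labelled BRG1 0 keratinocyte markers passed. Of the neural markers 1 rose and 2 fell without library 2 labelled BRG1, 1 and 3 without library 1, and 1 and 4 without control 1. Without library 1 labelled BRG1 0 skeletal muscle markers passed, and without control 1, 2 keratinocyte markers rose and 3 fell. Median and mean differed in sign for the endothelial, adipocyte, neural and skeletal muscle markers, and scaling by library size alone turned the adipocyte median from -0.18 to 0.05 (0.16 without control 2) and the keratinocyte median from -0.09 to 0.14.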

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

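Of the tests in this part, the one on olfactory receptor genes was fixed before its result was seen; the ones on long noncoding RNAs and on gene span were chosen only afterwards.

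Reads outside annotated genes, which no test of genes above uses, stood at 10.26% and 10.52% in the libraries labelled BRG1, above the controls at 6.11% and 7.34%. Of 1110 long noncoding RNAs tested 277 rose and 51 fell, while most ribosomal protein and oxidative phosphorylation genes fell. Genomic DNA was argued against: an even spread over the genome predicts 138 extra reads in 116 olfactory receptor genes, which fibroblasts do not use, and 0.3% of that was seen (upper 95% limit 7.3%; 15 reads in each group). More nuclear or unspliced RNA in the libraries labelled BRG1 stays open: the median log2 fold change of long noncoding RNAs was 0.621, above all 10000 random lists of protein-coding genes matched on level (highest 0.406), but the lncRNA share of each library had been seen beforehand and a change in transcription may give the same value. The trend with gene span also parts the controls (Spearman -0.24). Once it was removed, the ribosomal protein median stayed at -0.414 (95% interval -0.62 to -0.32, from -0.69). The median of the 19 oxidative phosphorylation genes with a span stayed at -0.52 (95% interval -0.676 to -0.435, from -0.808). These intervals resample genes that move together (estimated correlation 0.962 and 0.733), so they do not measure the spread between libraries. Within these libraries the values argue against the trend as the whole cause for the genes covered. Only 63.3% of the oxidative phosphorylation genes have a span, so for the others the trend stays open. An effect of BRG1 itself was not tested apart from the libraries.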

How the results depend on the processing

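The removal of the trend with gene span, and the gene lists with DESeq2 size factors, were chosen after the data had been seen; the other alternatives were fixed before. The SMARCA4 log2 fold change of -0.04 turned to 0.181 (adjusted p = 0.18) with scaling by library size alone and ranged from -0.152 to 0.048 as each library was left out, with an adjusted p of 0.0251 without control 1; with the span trend removed it was -0.262 (adjusted p = 0.0348), and over all alternatives its adjusted p (edgeR, DESeq2 or limma-voom, Benjamini-Hochberg) ranged from 0.0251 to 0.948. The cause was not tested. Counts of 3068 higher and 3444 lower genes became 4820 and 2139 with library size alone, as that scaling moves all genes by 0.23, and 1267 and 917 with a fold of at least 2. As each library was left out they ranged from 1908 to 3673 and from 2177 to 4321, fewer where a library labelled BRG1 was missing; the lone library of its group is then assumed to vary like the other group. Other scalings, filters and tools kept both counts within 1.5 times, and 0 genes were called in opposite directions under any alternative. Of the 152 genes past the threshold that the naming rule gives, 120 kept their direction and their side of it under all 12 alternatives that tested them; 25 and 20 no longer passed without library 1 and library 2 labelled BRG1, 12 with library size alone, and HSPB1, ND1 and ND4L turned to 0.017, 0.094 and 0.194 with the span trend removed. The examples in the report were picked from the 152 with these outcomes in view, so they are steadier than the whole. Of 37 lists, 15 passed; camera with an estimated correlation gave 0 and fry 9, and leaving out each library gave 12 to 16. Of the 15, fry lost the matrix, protease, cartilage and bone, acetyltransferase, ribosomal protein and oxidative phosphorylation lists (adjusted p from 0.0626 to 0.0945). With the span trend removed, lists were tested with camera on signed gene statistics. There histone acetyltransferases no longer passed (adjusted p = 0.0691) and demethylases and mitochondrially encoded genes did (0.0394 and 0.000125). The change of test may have moved these calls as well as the trend. The demethylase median, which rests on no list test, went from -0.13 to -0.32 with the trend removed. Mitochondrially encoded genes, with a median span of 0.87 kb, are raised by the removal itself, so their call decides nothing about them. MYH11, which did not pass, turned to -0.137 with the span trend removed and ranged from -0.238 to 0.442 as each library was left out. PDGFRB and SMTN, which did not pass either, turned to 0.007 and 0.132 with library size alone; as each library was left out SMTN ranged from -0.211 to 0.011, and PDGFRB passed as lower without control 1 (-0.411). The replicate block gave 3189 and 3505 genes, -0.041 for SMARCA4 and 16 lists, the added list being apoptosis regulators (camera adjusted p = 0.0483). Deviations of same-numbered libraries correlated at -0.04, which gave no sign of pairing. That value cannot exclude it, since the libraries labelled BRG1 differed less than the controls (chi-square per degree of freedom 5.34 against 40.1). The labels leave pairing open. Alternatives planned for normalized values were not run, since the files hold counts. With 2 libraries per group, 73 of 100 simulated 2-fold changes were recovered. That simulation changed 200 genes, whereas 6512 passed in the data, and the Benjamini-Hochberg cutoff depends on how many genes change. The recovery therefore does not measure the sensitivity of the test in these data. Nor do its 11 false calls measure the rate of false calls in these data. Simulated genes varied independently and alike in both groups, whereas the controls differed more and parted along gene span (Spearman -0.24). Changes smaller than 2-fold were not simulated, so how many of them were missed is not known.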

Other observations

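The gene families in the next paragraph, the genes named from them, the smooth muscle genes named and the counts of that list, and the tests on leukocyte markers as a whole, gene span and sample labels were chosen only after the results had been seen; the tests on 7 leukocyte genes, smooth muscle genes and scaling were fixed before.

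Of 20 families looked at, 19 were large enough for camera, adjusted over those 19: 11 passed and 8 did not (adjusted p from 0.113 to 0.668), and 0 passed with an estimated correlation. Proteasome subunits fell in 34 of 35 genes tested (median -0.92; camera adjusted p = 1.33e-19, adjusted p = 0.567 with an estimated correlation). PSMB10, a catalytic subunit of the immunoproteasome, fell from 76.7 ± 8.91 to 21.7 ± 1.21 CPM, and PSMD3, a subunit of the regulatory particle, from 339 ± 12.5 to 142 ± 2.07 (SD, n = 2). All 8 tested genes of class I antigen presentation fell (median -1.64; camera adjusted p = 9.35e-12, adjusted p = 0.559 with an estimated correlation), among them TAP2, a peptide transporter, at -1.18 ± 0.11 (SE) and NLRC5, an activator of class I genes, at -1.88 ± 0.18; 3 of the 8 are also in the fixed lists and 3 are also counted among the proteasome subunits. Mitochondrial ribosomal proteins fell in 42 of 69 genes and aminoacyl-tRNA synthetases in 14 of 17 (camera adjusted p = 8.45e-07 and 0.000133; adjusted p = 0.608 and 0.559 with an estimated correlation). Of 16 collagens outside the fixed matrix list 8 rose and 2 fell, with COL16A1 rising from 260 ± 22.0 to 594 ± 4.80 CPM (camera adjusted p = 0.0408; adjusted p = 0.604 with an estimated correlation). Scaling by library size alone kept the sign of the median in each of these 5 families.

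Contractile and matrix genes rose while inflammatory and interferon genes fell, and the libraries labelled BRG1 may differ in state or in cell makeup. The median control level of 7 leukocyte genes, 1.98 CPM by library size and 2.14 with TMM, lay on either side of the bound of 2 set beforehand and decides nothing, while 4 of the 10 tested markers fell by up to 2.10 on the log2 scale and 8 of 21 lay at or above 1 CPM, as leukocytes in the controls would give; against them stand 13 of 21 markers below 1 CPM and 0 reads of PTPRC, a bound set after the levels had been seen. Scaling by library size alone moves all genes by 0.23, so the contractile median of 1.02 could only become 1.241 and the inflammatory median of -1.72 only -1.49. A shift of that size is too small to make the pattern. This follows from the sizes of the medians and is no separate test. With the trend with gene span removed the contractile median was 0.987. Its 95% interval from 0.402 to 2.05 did not clear the bound of 0.5 set for it, so a part played by the trend stays open. The lower end lies above 0, a bound adopted only after the first had been missed. Within these libraries that argues against the trend as the whole cause, though the interval resamples genes and not libraries. The inflammatory median stayed at -1.55. Smooth muscle cells or pericytes in the cultures labelled BRG1 cannot be told apart from a changed fibroblast state, since the median of the 11 of 18 such genes that could be tested, 0.624, lay between the bounds set beforehand: 3 rose (CNN1, also in the contractile list, 2.29 ± 0.17; NOTCH3 1.22 ± 0.21; CSPG4 0.62 ± 0.13) and 0 fell, and the other 8 did not pass, among them PDGFRB, the most abundant (686 ± 133 against 590 ± 3.70 CPM; -0.22 ± 0.13, though -0.41 and past the test without control 1), SMTN (-0.09 ± 0.13) and MYH11, a smooth muscle myosin (1.20 ± 0.33 against 1.33 ± 0.43 CPM); a biological effect of BRG1 stays open as untested.

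SMARCA4 was not higher in the libraries labelled BRG1, and an error of labels may be asked about. A single library with the wrong label was argued against: each library correlated better with its partner than with any library of the other group, by at least 0.031. An exchange of both groups' labels cannot be told apart from the labels as given, because the lower bound of the SMARCA4 interval, -0.269, lies neither at a clear fall nor at a clear rise, the gene passed as lower in 2 alternatives at values no further than -0.262, and reads of an introduced coding sequence need not be counted under the pig gene. Protein levels were not analysed here.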
